A study of Rattus norvegicus with 26 samples.

How the data were processed

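Gene expression was measured by RNA sequencing in rat hepatocytes before transplantation (16 libraries) and in laser-captured liver tissue after it (10 libraries). Per the labels' protocols, RNA of adult and sorted fetal cells went into a library kit for purified RNA (NEBNext Ultra), and RNA of captured tissue into a stranded total RNA kit for very small inputs (SMARTer Pico). Kit, material and capture change together between the stages, so no level was compared across them and only differences within a stage were set against each other.

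The deposited values are raw counts per feature as the authors' counting gave them, per the file headers, with each feature's exon coordinates and length. Per the submitters' processing notes the tools were bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2. The genome build, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and near-identical copies may share reads. The features carry identifiers only. The reference table of 47357 genes used here pairs 0 of the 32552 identifiers with a symbol. The lists of marker and pathway genes fixed beforehand could therefore not be tested, and no gene is named. Positions are as deposited.

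Groups were taken from the sample titles. Host and colony libraries share the number of their animal, and the animal was kept as a block in that comparison. Numbers before transplantation are called biological replicates in the labels, which do not say that equal numbers share an animal or litter. No block was used in the main test there. Host and colony deviations from their group means correlated between -0.22 and 0.44 within animals (over 0.1 in 3 of 5), and the block was kept because the labels give the same animals. How regions were chosen for capture is not given in the sources used here. No replicate pair of 44 agreed within sampling noise (chi-square per degree of freedom from 4.91 to 255).

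Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F test) and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. Colony and host were tested on their 10 libraries, the groups before transplantation on all 16 in 1 fit, and the difference of differences on all 26. Genes with an adjusted p under 0.05 and an absolute log2 difference of at least 1 between the fetal mean and adult cells formed the fetal-higher and adult-higher sets, which share no library with the colony comparison. Sets were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation. CPM values use TMM-scaled library sizes in the gene-level values, and shares and abundance ranks use nuclear counts alone (nuclear CPM). Lower bounds for genes without a count use library totals without TMM scaling. The score adds 1 to each CPM before the log. Neighbouring runs hold at least 4 tested genes called in 1 direction with gaps of at most 500000 nt, set against 1000 shuffles. Single values of libraries were tested with exact permutation tests in scipy 1.17.1.

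The choices of test, design, filters, alternatives and the rule for genes to name were made before the data were examined. The rule takes, among genes past the adjusted p with at least 10 CPM in the higher group and the same sign in every animal or groups that do not overlap, those with the largest change. Its conditions on gene symbols and lists could not be applied, and only the 2 highest and 2 lowest genes per comparison are printed. Groups by length, chromosome, abundance and runs, and the trace gene sets, were chosen after the data were examined. Alternatives included RLE size factors, other low-count filters, DESeq2 1.42.0, limma-voom with quality weights, fits with and without the block, and leaving out each library or animal in turn.

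The edgeR test was tried on simulated data with 200 genes changed. This was done for colony against host, the fetal mean against adult, the OC2 sorts and the difference of differences. The other comparisons, camera and the shuffles were not simulated. The real fit of the fetal mean against adult called 10010 genes, so scaling and error rates under so many changes were not tested. The changed genes were drawn only above a minimum mean CPM, and the simulated libraries had no differences between animals. Recovery of lower genes, and in the real libraries, can therefore be less than given here. A 2-fold change (log2 of 1) was recovered in 78% of cases for colony against host, 83% for the fetal mean against adult, 60% between the OC2 sorts and 46% for the difference of differences. In the colony simulation, 10.6% of calls were false. A library total of 7871347 to 16874438 counts puts the limit that a count of 0 allows, 3 counts, at 0.178 to 0.381 CPM. Intervals and such limits cover counting error only.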

Results

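RNA was measured in rat liver by sequencing in 26 libraries that fall into 6 groups. Before transplantation, 4 libraries came from adult hepatocytes and 12 from immunopurified fetal hepatocytes, in 3 sorts of 4 libraries each. The sorts carry the labels LAP+, LAP+/OC2+ and LAP+/OC2-, and the labels do not spell these markers out. After transplantation into adult liver, laser capture gave tissue of colonies that grew from fetal cells and of the adult host liver around them, both from the same 5 animals. The comparisons ask how fetal and adult hepatocytes differ before transplantation and how much of that difference is seen between colony and host. The deposited counts cover 32552 features, and totals per library ranged from 7871347 to 16874438. The features carry identifiers that the files do not pair with gene names, so groups are described here by chromosome, position, length and abundance.

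Fetal and adult hepatocytes differed in most of the genes measured before transplantation. Of 13818 genes tested, 5128 were higher and 4882 lower in the mean of the 3 fetal sorts than in adult cells, at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The 2 directions were close to even, with 5304 higher and 5323 lower without a low-count filter. At least 2-fold changes made up 3512 of the higher and 3060 of the lower genes. Changed genes lay beside each other in runs. At 2-fold, runs of at least 4 neighbouring genes held 380 of the fetal-higher genes, against a median of 154 and a maximum of 227 in 1000 shuffles of the calls along the genome. For fetal-lower genes the runs held 260 genes, against a median of 90 and a maximum of 156 (permutation p = 0.001 in both directions, the smallest that 1000 shuffles can give).

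The longest run lay on chromosome 6 between 133552821 and 133898905 (coordinates as deposited, genome build not given in the sources used here). All 31 of its tested genes were higher in fetal cells, with a fitted median log2 difference of 5.38. As 13 of them had no count in the adult libraries, the median was 3.94 with those genes set to the lower bound that 3 counts per library allow. Their summed mean level was 1522 CPM in LAP+ cells and 14.4 CPM in adult cells. A run of 9 genes on chromosome 15, from 34601037 to 35113678, was higher in fetal cells by a median log2 of 5.63, and by the same median with 1 gene set to its lower bound. On chromosome 5, from 77245143 to 78131114, 8 neighbouring genes were lower in fetal cells by a median log2 of -9.74, and their summed mean level was 4939 CPM in adult and 4.46 CPM in LAP+ cells. Each of these genes had a count in some fetal library, so no lower bound was applied. The fitted size is uncertain where LAP+ counts lie near 0. A run of 10 genes on chromosome 20, from 3973420 to 4508214, was lower by a median log2 of -2.75. Nuclear features shorter than 200 nt were higher in fetal cells in 131 of 189 cases and lower in 15 (camera adjusted p = 1.9e-04, and adjusted p = 0.98 with an estimated correlation).

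Under the rule for named genes, the largest fall was in ENSRNOG00000045799 (chromosome 8, 41657566 to 41661238), at 4923 ± 2115 CPM in adult cells (SD, n = 4) and 0.013 ± 0.026 CPM in LAP+ cells (SD, n = 4). Its fitted log2 difference for the fetal mean was -10.88 (SE 0.35, edgeR adjusted p = 7.9e-14). It stood at 24.8 ± 9.91 CPM in LAP+/OC2+ and 35.0 ± 8.69 CPM in LAP+/OC2- cells (SD, n = 4 each). The size of the fitted difference rests largely on LAP+ cells, where library 1 had 0.051 CPM and the others had no count. No lower bound was applied to it. ENSRNOG00000050232 (chromosome 8, 37702231 to 37705044) had the next largest fall, at 1612 ± 721 CPM in adult cells (SD, n = 4) and no count in any LAP+ library. Among the higher genes, ENSRNOG00000038133 (chromosome 16, 75517505 to 75518336) had no count in the 4 adult libraries, while LAP+/OC2+ cells stood at 39.0 ± 2.04 CPM (SD, n = 4). In LAP+ cells its mean of 12.5 CPM rested on library 4, at 48.2 CPM, against at most 0.66 CPM in the other LAP+ libraries. On CPM without TMM scaling, the fetal mean was at least 74.97-fold higher than 3 counts per adult library. Its call was lost without the LAP+/OC2+ libraries (edgeR adjusted p = 0.061). ENSRNOG00000060320 (chromosome 5, 152230343 to 152247332), also without an adult count, stood at 51.1 ± 29.1 CPM in LAP+/OC2+ cells (SD, n = 4), and its fetal mean was at least 56.0-fold higher by the same measure.

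Each sort also differed from adult cells when tested alone. The edgeR test called 8330 genes for LAP+ cells, with 4387 higher and 3943 lower. It called 10707 for LAP+/OC2+ cells, with 5369 higher and 5338 lower, and 8192 for LAP+/OC2- cells, with 4266 higher and 3926 lower. Which direction held more genes was not stable. For LAP+/OC2- cells it turned to 4012 higher and 4155 lower with RLE size factors and to 4181 and 4369 with DESeq2. For LAP+/OC2+ cells it turned with the stricter low-count filter (5150 and 5171) and without any 1 of the 4 libraries of this sort (5331 and 5492 without library 1).

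The LAP+/OC2+ sort stood apart from both other fetal sorts. Mitochondrial features took 62.2 ± 17.9% of its counts (SD, n = 4), against 4.94 ± 0.70% in LAP+/OC2- and 5.04 ± 0.98% in LAP+ cells (SD, n = 4 each; 2-sided exact permutation p = 0.029 for each difference, the smallest that 4 against 4 libraries allow, and 0.036 after Benjamini-Hochberg adjustment over 5 tests). All 13 mitochondrial features longer than 200 nt and all 17 tested shorter ones were higher than in LAP+/OC2- cells, the longer ones by a median log2 of 4.90 (camera adjusted p = 7.6e-10, and adjusted p = 0.67 with an estimated correlation). The LAP+/OC2+ libraries held 1917734 to 5045098 nuclear counts. The share was 1.05 ± 0.30% in colonies and 0.72 ± 0.17% in hosts (SD, n = 5 each; 2-sided exact sign-flip p = 0.25).

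**Figure D1:**
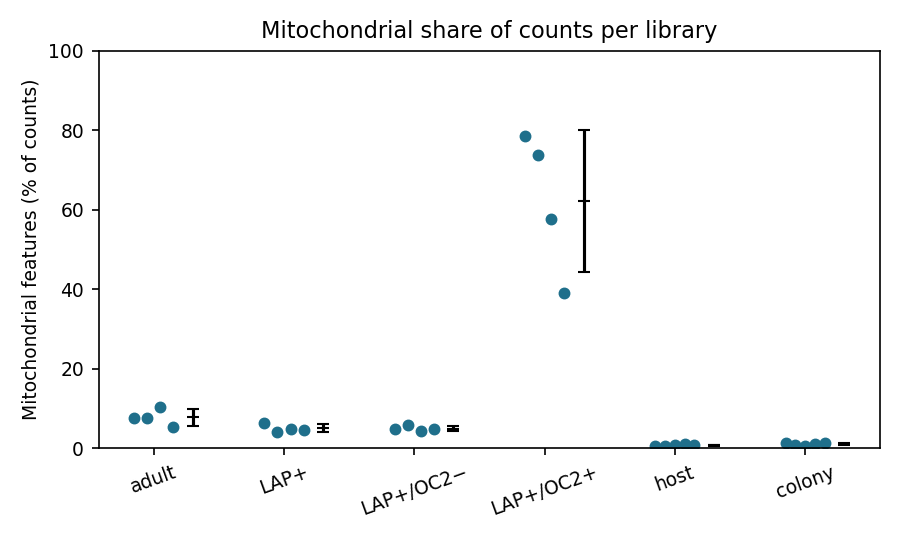
Share of counts on mitochondrial features (y axis, percent) for each library of the 6 groups (x axis), with 1 point per library and the mean ± SD as a bar beside each group. The 4 LAP+/OC2+ libraries lie at 78.6, 73.7, 57.6 and 38.9%, and no other library exceeds 10.3%.

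Nuclear genes separated the sorts as well. Against LAP+/OC2- cells, 4261 genes were higher and 5062 lower in LAP+/OC2+ cells at an adjusted p under 0.05. Genes abundant in the other cells were lower. Of the 50 most abundant nuclear genes of adult hepatocytes, a group that does not enter this comparison, 43 were lower and 0 higher, with a median log2 difference of -3.03. The 20 most abundant nuclear genes of each library took 19.9 ± 2.21% of its nuclear counts in LAP+/OC2+ and 37.8 ± 2.72% in LAP+/OC2- cells (SD, n = 4 each; 2-sided exact permutation p = 0.029, adjusted p = 0.036). The most abundant gene differed too. In adult, LAP+ and LAP+/OC2- cells it lay on chromosome 14 from 19176277 to 19191863, with 11.7, 10.9 and 10.5% of nuclear counts. In LAP+/OC2+ cells it lay on chromosome 10 from 15602794 to 15603649, with 4.83 ± 1.93% (SD, n = 4).

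Runs of neighbours held 258 of the genes at least 2-fold higher and 396 of those at least 2-fold lower in LAP+/OC2+ cells, against medians of 88 and 161 in shuffled calls. Among the higher runs, 4 lay on chromosome 17 between 43617247 and 44815995. On chromosome 11, from 81421676 to 81794580, 6 neighbours were lower by a median log2 of -3.05, and on chromosome 13, from 56598957 to 57080622, 6 were lower by a median log2 of -3.78. ENSRNOG00000056387 (chromosome 8, 79679458 to 79679541) stood at 22.3 ± 11.4 CPM in LAP+/OC2+ cells (SD, n = 4) with no count in the LAP+/OC2- libraries. On CPM without TMM scaling (mean 12.8) it was at least 68.3-fold higher than 3 counts per library. ENSRNOG00000053656 (chromosome 4, 163628640 to 163649637) stood at 42.6 ± 22.1 CPM (SD, n = 4) against 0.012 CPM. ENSRNOG00000046365 (chromosome 20, 29009330 to 29029905) fell from 63.4 ± 29.6 CPM in LAP+/OC2- to 1.39 ± 0.74 CPM in LAP+/OC2+ cells (SD, n = 4 each; log2 difference -5.67, SE 0.53, edgeR adjusted p = 1.0e-07). ENSRNOG00000038948 (chromosome 7, 27369853 to 27552078) fell by 4.95 on the log2 scale (SE 0.52, edgeR adjusted p = 4.3e-07). Counts against LAP+ cells were similar in size, with 4417 genes higher and 4956 lower, but turned to 4813 higher and 4544 lower with RLE size factors and to 4924 and 4618 with DESeq2. Size factors by the RLE method moved the median log2 difference between the OC2 sorts from -0.18 to -0.05 and gave 4682 higher and 4553 lower genes, and DESeq2 gave 4760 and 4639.

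LAP+/OC2- and LAP+ cells differed in few genes, 34 higher and 20 lower in LAP+/OC2- cells (edgeR), and the 54 calls became 98 without LAP+ library 2 and 95 without LAP+ library 3. Without LAP+ library 2 the direction turned, to 35 higher and 63 lower. Of the 34, 30 had an adult level over 10 times that of LAP+/OC2- cells, and their level in LAP+/OC2- cells was a median 0.794% of the adult level. The 20 lower genes had a median level of 6.29 CPM in LAP+, 0.613 CPM in LAP+/OC2- and 19.7 CPM in LAP+/OC2+ cells. For 19 of them every LAP+ library lay above every LAP+/OC2- library, a gap that their choice on these same libraries favours. The highest LAP+ level was in library 1 for 13 and in library 4 for 7. Without library 1 and without library 4, 18 and 16 genes were called lower. A set of 14 genes, above 100 CPM in every adult library and under 0.05% of the adult level in LAP+ cells, showed the same trace levels. Its median level per library averaged 0.965 ± 0.339% of adult in LAP+/OC2- and 1.02 ± 0.326% in LAP+/OC2+ cells (SD, n = 4 each), and 0.0019 ± 0.0030% in LAP+ cells (SD, n = 4), where the choice of genes fixes a low value.

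**Figure D2:**
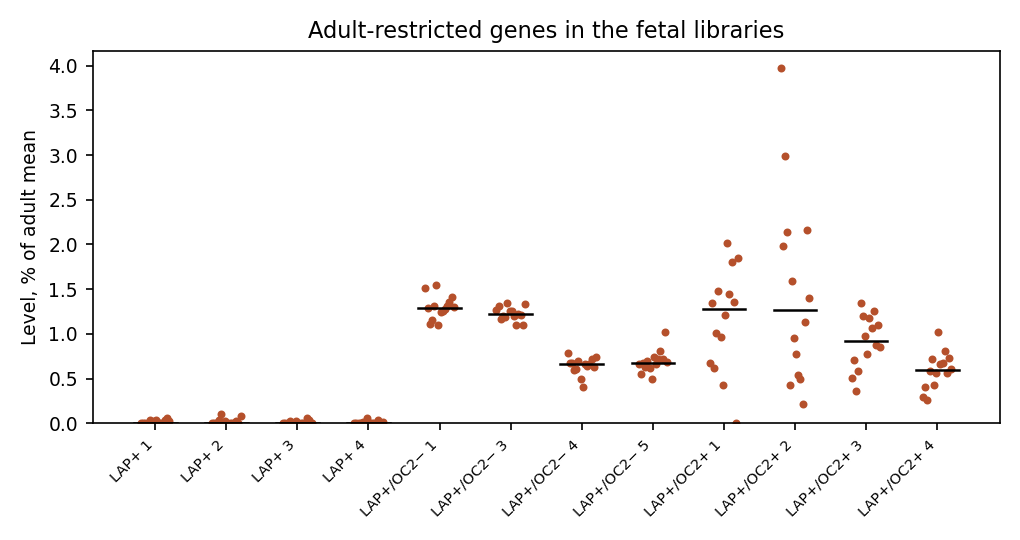
Level of 14 genes restricted to adult cells (y axis, percent of the adult mean CPM) in each of the 12 fetal libraries (x axis), with 1 point per gene and a line at the median. The 4 LAP+ medians lie at or below 0.0062%, and those of the 8 libraries sorted on OC2 lie between 0.592 and 1.29%.

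Colony and host tissue differed little beside these contrasts. With the animal as a block, the edgeR test called 126 genes higher and 136 lower in colonies among 22303 tested, at an adjusted p under 0.05. Genes with over 5000 nt of exon made up 68 of the 126 higher calls and 6 of the lower calls. As a class these 1899 genes did not rise, with a median log2 difference of -0.01 (camera p = 0.63, and p = 0.80 with an estimated correlation). Changes of at least 2-fold were called for 89 higher and 4 lower genes. On chromosome 14, from 22142364 to 22619968, 4 neighbouring genes were lower in colonies by a median log2 of -0.56, and no run of 4 lower genes arose in 1000 shuffles (permutation p = 0.001, the smallest that these shuffles can give). In the cells before transplantation these 4 genes summed to 1875 CPM in adult and 171 CPM in LAP+ libraries.

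Under the rule for named genes, the 2 largest rises were of long genes with many exons. ENSRNOG00000042899 (chromosome 1, 85058548 to 85096346) stood at 10.6 ± 3.30 CPM in colonies and 4.35 ± 2.55 CPM in host tissue (SD, n = 5 each; log2 difference 1.43, SE 0.29, edgeR adjusted p = 0.017). ENSRNOG00000004560 (chromosome 3, 1740024 to 1924827) stood at 17.1 ± 4.39 and 6.61 ± 2.64 CPM (SD, n = 5 each; log2 difference 1.42, SE 0.23, edgeR adjusted p = 0.0022). ENSRNOG00000009730 (chromosome 2, 102701903 to 102871257) fell by 1.08 on the log2 scale (SE 0.25, edgeR adjusted p = 0.024), and ENSRNOG00000053795 (chromosome 2, 260115160 to 260115240) fell by 1.07 (SE 0.23, edgeR adjusted p = 0.031). These calls were fragile. All 4 genes lost theirs without the block on the same 22303 genes, without animal 242 and without animal 249. With the stricter low-count filter ENSRNOG00000042899 (edgeR adjusted p = 0.071), ENSRNOG00000009730 and ENSRNOG00000053795 (0.077 each) lost theirs, and 4 genes were called higher and 2 lower. The count of all calls by edgeR was 0 without the block on the same genes (3483 at an unadjusted p under 0.05) and 0 without animal 249 (2225 at that p), 5 without animal 242, 130 without animal 243, 158 without animal 248 and 2683 without animal 246. The direction with more calls turned without animal 243 (70 higher, 60 lower) and without animal 248 (107 higher, 51 lower). With all animals and the block, 4235 genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 717 and 3274.

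Genes that separated fetal from adult cells before transplantation leaned the same way in colonies, by a small amount. The 3342 fetal-higher genes had a median log2 difference of 0.20 between colony and host, with 66.8% higher in colonies (camera p = 1.6e-21, and p = 0.012 with an estimated correlation). The median fell to 0.13 without animal 248. All 22303 genes tested had a median of 0.11, but the sets were drawn from the 13517 genes tested in both fits. On those, the median differences of log2(CPM + 1) were -0.17, -0.08, 0.03, -0.05 and -0.15 in animals 242, 243, 246, 248 and 249. The 3048 adult-higher genes had a median of -0.22, with 18.9% higher (camera p = 3.6e-14, and p = 0.17 with an estimated correlation). Colony-host medians also varied with expression level and feature type, whose part in the lean was not assigned. Nuclear features of 1 exon and at least 200 nt had a median colony-host difference of 0.59, and nuclear features under 200 nt one of 0.41. Among genes with a mean of at least 10 CPM in the post-transplant libraries, 988 fetal-higher genes had a median of -0.05 and 2341 adult-higher genes one of -0.25. Across the 13517 genes tested in both fits, which are not independent replicates, the log2 differences before and after transplantation correlated with r = 0.43 (rho = 0.43). The correlation was 0.31 for genes of at least 10 CPM and 0.27 after regression on level, exon length and exon number. Single colony or host libraries, each set against the others of their own group, gave r from -0.30 to 0.33 with the same pre-transplant differences.

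By gene, 31 fetal-higher genes were called higher in colonies, where independent lists would share 11.1, and 98 adult-higher genes were called lower, where they would share 30.2. In the opposite directions there were 3 and 3 calls. These 129 same-direction calls fell to 0 without animal 242, without animal 249 or without the block on the same genes, to 47 without animal 243 and to 53 without animal 248, and rose to 1136 without animal 246. Of the 50 genes most abundant in adult hepatocytes, 48 had a negative colony-host difference and 3 were called lower, with a median log2 difference of -0.38. Of the genes most abundant in LAP+ cells, 44 of 49 tested also had a negative difference and 1 was called lower (median -0.32). Of those most abundant in LAP+/OC2+ cells, 34 of 49 did and 0 were called (median -0.13).

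The animals were not alike. A signature score was taken per library as the mean log2(CPM + 1) of fetal-higher genes minus that of adult-higher genes. Before transplantation it was -3.19 ± 0.09 in adult, -0.31 ± 0.09 in LAP+, -0.37 ± 0.12 in LAP+/OC2- and 1.43 ± 0.27 in LAP+/OC2+ cells (SD, n = 4 each), on libraries that also defined the genes. After transplantation, colonies scored 0.36 ± 0.29 above their hosts (SD, n = 5), which was 10.5% of the gap between the fetal mean and adult cells. The score was higher in the colony in 4 of 5 animals, and the difference did not pass a 2-sided exact sign-flip test (p = 0.125, where 5 animals allow no p under 0.0625). Animal 246 went the other way, by -0.11.

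**Figure D3:**
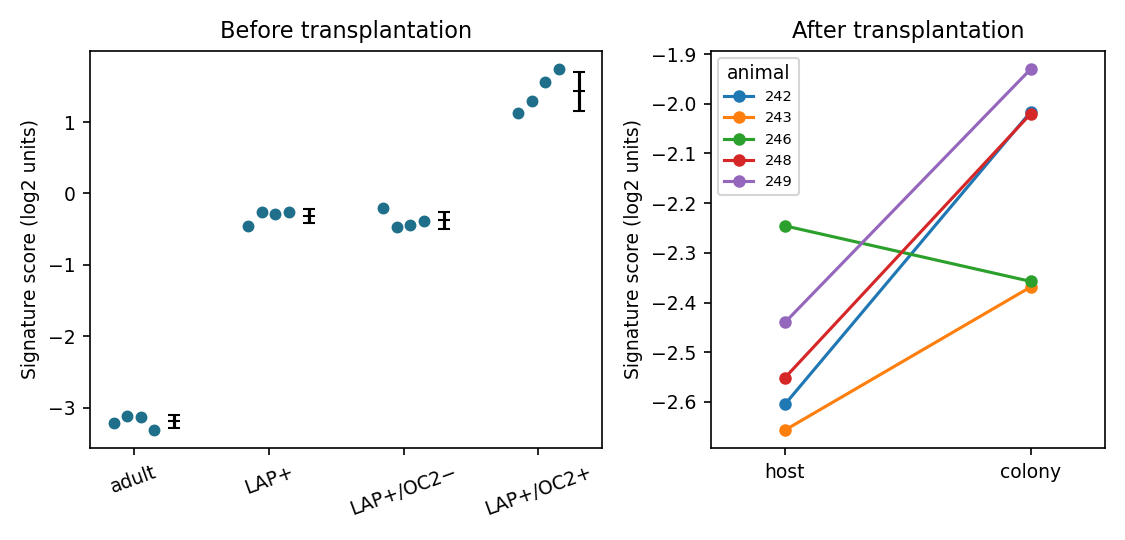
Signature score per library (y axes, log2 units, with different ranges in the 2 panels). The left panel shows the 4 groups before transplantation with the mean ± SD as a bar beside each group, and the right panel joins the host and colony libraries of each of 5 animals. The colony lies above the host in 4 animals and below it in animal 246.

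Of the 71 runs that were higher in fetal cells before transplantation, 50 had a positive median difference in colonies. Of their 327 genes tested there, 65.7% had a positive difference, close to the share among all fetal-higher genes, and 1 was called higher. Of the 56 runs that were lower in fetal cells, 51 had a negative median, with 17 of 260 genes called lower and 1 higher. Single runs, looked at after the data were seen, differed. In the chromosome 6 run, 9 genes were tested after transplantation, all with a positive difference and a median log2 of 1.63, and none was called. In the chromosome 15 run, all 9 tested genes had a positive difference with a median of 1.26, and 1 was called. These 2 medians were the largest among the longest fetal-higher runs. The others, on chromosomes 17, 20 and 10, had medians of 0.22, 0.30 and 0.04. Those on chromosomes 13, X and 1 had negative medians, of -0.38, -0.18 and -0.96. In the chromosome 20 run of adult-higher genes, all 10 had a negative difference with a median of -0.36, and 1 was called. The 8 adult-higher genes on chromosome 5 had a median of -0.01.

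The difference between colony and host was tested against the difference between fetal and adult cells in 1 fit of all 26 libraries. It differed for 7859 of 23459 genes (edgeR), with 3328 higher and 4531 lower. The excess of lower genes shrank with RLE size factors (3775 higher, 4019 lower), with the stricter low-count filter (3627, 3816) and without animal 248 (3835, 3847). Because the sets were chosen on the libraries before transplantation, their differences there are enlarged by the choice. Of the fetal-higher genes, 2745 of 3342 had a smaller difference after transplantation, 0 a larger one and 597 neither. Of the adult-higher genes, 2725 of 3048 had a smaller difference and 0 a larger one. Size factors by the RLE method and DESeq2 moved the median of all genes from -0.04 to 0.09 and 0.11. Median log2 differences of the sets went from 2.05 before to 0.20 after transplantation for fetal-higher genes and from -1.84 to -0.22 for adult-higher genes. The libraries before and after transplantation were made with different kits from different material, so levels were not compared between them directly. ENSRNOG00000052810 (chromosome 1, 257970345 to 258004434) had no count in LAP+ cells and 1788 ± 1221 CPM in adult cells (SD, n = 4), and stood at 871 ± 144 CPM in colonies and 1073 ± 242 CPM in host tissue (SD, n = 5 each). ENSRNOG00000047613 (chromosome 5, 77744450 to 77749613) had no count in LAP+ cells either and stood at 191 ± 155 CPM in colonies and 178 ± 154 CPM in host tissue (SD, n = 5 each). In the other direction, ENSRNOG00000038133 stood at 0.19 ± 0.16 CPM in colonies (SD, n = 5) and ENSRNOG00000050110 (chromosome 11, 67465236 to 67470941) at 0.33 ± 0.31 CPM (SD, n = 5). Both calls were lost without the LAP+/OC2+ libraries (edgeR adjusted p = 0.13 and 0.092), without animal 246 (0.081 and 0.080) and without animal 248 (0.16 and 0.080). The first was also lost with RLE size factors (0.052), without animal 242 (0.074) and without animal 243 (0.076), and the second with limma-voom (adjusted p = 0.071).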

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

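Of the tests in this part, those on level and gene length, on mitochondrial share, on the spread of trace levels, on carry-over in LAP+/OC2+ libraries and on exchanged labels in animal 246 were chosen only after the result was seen. A regression close to the one on level and gene length had been seen before it was written.

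Among 68 groups of values, 9 had 1 library far from the rest. Chance gives about 1 in 20 for values spread normally. That rate does not hold for CPM of genes near 0, so an excess over chance was not shown. The host library of animal 248 detected 19581 features, against 25648 to 27547 in the other hosts. The colony library of animal 248 had 34.9% of nuclear counts in its 20 most abundant genes, against at most 31.6% in the other colonies, and 165 nuclear CPM on the Y chromosome, against at most 127. Adult library 2 had 3.82 nuclear CPM on the Y chromosome, against 123 to 145 in the other adult libraries. It also lay below them, though not among the 9, in the 2 printed genes with the largest falls. It had 1857 nuclear CPM of ENSRNOG00000045799, against 5552 to 6744, and 600 of ENSRNOG00000050232, against 1786 to 2367. The adult SDs of these genes include this library. LAP+ library 4 had 48.2 CPM of ENSRNOG00000038133 and 4.41 CPM of ENSRNOG00000060320, against at most 0.66 and 0.62 in the other LAP+ libraries. LAP+ library 1 had 0.051 CPM of ENSRNOG00000045799 and LAP+/OC2- library 3 had 0.046 CPM of ENSRNOG00000053656, where the others had 0. LAP+/OC2- library 3 also had 108 CPM of ENSRNOG00000038948, against 48.0 to 55.3.

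The difference between colony and host differed from that between fetal and adult cells for 7859 genes. For the genes printed, the fitted differences of log2 differences were 10.39 for ENSRNOG00000052810, 10.30 for ENSRNOG00000047613, -10.86 for ENSRNOG00000038133 and -8.59 for ENSRNOG00000050110. These fitted values depend on the prior count where a group has no counts. Of 60 drawn splits 1, the real one, reached the count, and the highest of the others gave 32. These splits also remove the difference between fetal and adult cells itself. They therefore cannot show whether the differences before and after transplantation are unequal beyond chance.

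The lean of the signature sets in colonies is the first pattern weighed: with level, exon length and exon number regressed out per animal, the difference of set medians went from 0.367 ± 0.295 to 0.109 ± 0.089 (mean ± SD over 5 animals, positive in 4), which argues against these properties as the whole source of the lean, while the part removed is not assigned to them because the sets themselves differ in level. Chance cannot be excluded. Of 100 drawn splits, 23 gave as large a set difference as the real 0.414 (highest other 0.671). As many calls as the real 262 came in 9 (highest other 2919), and as many same-direction calls as the real 129 in 9 (highest other 1246). Splits with so many calls point to a structure of the samples. Most of the drawn splits put both libraries of some animals on 1 side, so the blocked test rests on fewer animals there. They are not a null for the paired result. The 16 splits that part every animal's libraries are too few for a share under 0.05; 2 reached each real value, the other being the exchange of animal 246, with 1868 calls, a set difference of 0.480 and 857 same-direction calls. Exchanged labels may explain animal 246, whose host score of -2.25 lay above the other hosts (-2.66 to -2.44), and exchanging them raised the calls. Its colony score of -2.36 lay inside the range of the other colonies (-2.37 to -1.93), which by the rule written for exchange goes against it. As a host score, -2.36 would also lie above the other hosts. These values point both ways, so exchange and a real difference of this animal cannot be told apart. Persistence of fetal expression stays among the open explanations, as does a different mix of cells in the captured tissue, which was not tested because no marker could be named.

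The mitochondrial share of the LAP+/OC2+ libraries is the second pattern. Inflation of nuclear differences that grows with the share inside the sort is argued against. The SD of nuclear log2 differences was 0.754 times as large in the 2 most mitochondrial libraries as in the other 2. It rose from 1.215 to 1.381, 1.608 and 1.835 as the share fell from 78.6 to 73.7, 57.6 and 38.9%. All 4 libraries lie far above LAP+/OC2-, so an effect of the share common to them cannot be tested within the sort. With nuclear counts of all 16 libraries thinned to 1917734, 4161 of 11206 genes tested still differed from LAP+/OC2- cells. That is below the 5000 set beforehand as excluding depth and above the 1000 set as needed for it. Unequal depth is argued against for these 4161 calls, since depth was equal there. Its part in the other calls cannot be told apart, as thinning every library also lowers the power of the test. Chance can be excluded for the split if libraries are taken as independent, with 9323 genes against 0 in the highest of the other 34 splits (1 of 35 as large). Cell state, the mix of cells, sort and RNA quality stay open, since all 4 libraries of the sort share them. The mix of cells was not tested because no marker could be named.

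Trace adult transcripts in the libraries sorted on OC2 are the third pattern. Low expression regulated gene by gene is argued against in the LAP+/OC2- sort, since the ratio to adult had an interquartile range of at most 0.179 log2 units over 14 genes in each library. Carry-over of adult reads at 1 rate per library is a candidate explanation there, since in 6 other adult-restricted genes the rate came within 0.302 log2 units of the first set's in every LAP+/OC2- library. For the LAP+/OC2+ libraries as a whole the explanations cannot be told apart. The rates of the sets came within 0.451 log2 units, as carry-over needs, on 27 to 45 counts of the second set. The interquartile range ran from 0.616 to 1.82 against the adult mean. Against the adult library of the same number it was 0.649, 0.343, 0.138 and 0.188 in libraries 1, 2, 3 and 4. The bound set for the sort, under 0.5 in all 4, was not met. Taken singly, libraries 2, 3 and 4 lie under it, which argues against low expression regulated gene by gene in them. Library 1 stays undecided. The rule first written for that second set (no count in LAP+ libraries) left 0 genes, and its limit was loosened to 0.2% of adult by the size of the set alone, and mixing of cells, of RNA and of reads remain open.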

How the results depend on the processing

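Alternatives on nuclear features, on features of 200 nt or more, without LAP+/OC2+ libraries and with the block changed on the same genes were chosen after seeing the data. Between colony and host, 262 edgeR calls became 0 without the block, where the filter follows the design and 18632 genes were tested, and 0 without the block on the same 22303 genes (3007 and 3483 genes at an unadjusted p under 0.05), 717 with DESeq2, 3274 with limma-voom, 6 with the stricter filter, 751 with no filter, 93 with a 2-fold limit, and 0 to 2683 with 1 animal left out. Same-direction signature calls (129) became 0 without the block, on either set of genes, and 342 with DESeq2, and ranged from 0 to 1136 with 1 animal left out. Opposite calls (6) became 0 and 13, and ranged from 0 to 67. The cause was not tested, except that fewer calls under the 2-fold limit follow from its construction. The adult-higher set kept its median of -0.22 with an estimated correlation, but not its call (p = 0.17). The 200 genes per direction with the smallest p had medians of 0.12 and -0.34. With 1 animal left out, the set medians ranged from 0.13 to 0.28 and from -0.29 to -0.18.

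The 2-fold limit left 6572 genes for the fetal mean, 5457 for LAP+ and 5276 for LAP+/OC2- against adult. Between LAP+/OC2- and LAP+ cells, 54 calls became 208 with DESeq2 and 171 with limma-voom, and ranged from 44 to 98 with 1 library left out. With nuclear counts thinned to the same depth, 14 were called (9 higher, 5 lower). Without LAP+ library 2 the count was 98, and without LAP+ library 3 it was 95. Counts of the other comparisons before transplantation and of the difference of differences stayed within 1.5 times of the main count under most alternatives. The exceptions were the 2-fold limits given and the thinned nuclear counts, with 4161 genes between the OC2 sorts against 9323 in the main fit. Before transplantation, no pair of groups had every same-numbered pair of libraries correlated over 0.1, and not every library correlated best with its own number. LAP+ libraries 2, 1, 3 and 4 correlated best with LAP+/OC2- libraries 1, 3, 4 and 5 (0.75, 0.65, 0.50 and 0.39), a hint of shared structure that the labels do not give and the test of 54 genes leaves out. The replicate number as a block gave 10102 genes for the fetal mean (9607 on the same genes) and moved no count by over 1.5 times. With libraries taken as independent, chance can be excluded for each comparison before transplantation except LAP+/OC2- against LAP+. There the splits leave out the shared structure between the libraries of these sorts, so they cannot decide. The real count was the 1 largest of 100 drawn splits for the fetal mean (10010, highest other 8671, a split that points to a structure among the libraries). It was the 1 largest of 35 splits for LAP+ (8330, highest other 5), LAP+/OC2+ (10707 and 34) and LAP+/OC2- (8192 and 30) against adult, for LAP+/OC2+ against LAP+ (9373 and 1) and for LAP+/OC2- against LAP+ (54 and 5). The alternative without marker list members was not run, because no identifier has a symbol. Nuclear depth of 1917734 to 5045098 counts limits what can be seen for low genes in LAP+/OC2+ cells.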

Other observations

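The values in this part were all chosen only after the data had been seen.

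Sets that separated the OC2 sorts were read in the colonies. The 2931 genes higher in LAP+/OC2+ than in LAP+/OC2- cells had a median colony-host log2 difference of 0.06, with 22 called higher and 7 lower in colonies (camera p = 1.8e-09, and p = 0.012 with an estimated correlation). The 3507 genes higher in LAP+/OC2- cells had a median of -0.19, with 4 called higher and 82 lower (camera p = 2.6e-06, and p = 0.25 with an estimated correlation). On chromosome 13, from 56598957 to 57080622, 6 neighbours that were lower in the fetal mean than in adult cells, by a median log2 of -3.01, all had a negative colony-host difference, and 3 of them were called.

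Across the 14 adult-restricted genes, which are not independent replicates, LAP+/OC2+ library 2 correlated best with adult library 2 (r = 0.92, against at most 0.53 with the other adult libraries). Adult library 2 itself lay apart from the other adult libraries in some of these genes, such as ENSRNOG00000010079 (143 nuclear CPM against 2713 to 3629). In ENSRNOG00000029844 it lay inside their range (222 against 148 to 294). For LAP+/OC2+ libraries 2, 3 and 4, the ratio to adult varied least between genes when set against the adult library of the same number, with interquartile ranges of 0.343, 0.138 and 0.188 log2 units, against at least 2.05, 0.385 and 0.405 with the other adult libraries. Library 1 varied less against adult library 4 (0.416) than against adult library 1 (0.649). All 4 LAP+/OC2- libraries varied least against adult library 4 among single libraries (0.291 to 0.426), and less against the mean of all 4 (0.087 to 0.179).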
